A study of Mus musculus with 6 samples.

How the data were processed

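Splenic B cells positive for CD19, the surface marker used to select B cells, were profiled by microarray in 1-month-old mice that carried the TCL1 transgene. The 6 arrays fall into 2 groups of 3 by the genotype in the labels, which is Id4 heterozygous or Id4 wild-type. Per the labels' protocols, total RNA was purified on columns and labelled enzymatically, and the mice were littermates of a first cross between TCL1 mice of C3H/B6 origin and Id4 heterozygous mice of CD1 origin. The array titles name 3 mice and a replicate number, and nothing in the labels says whether the arrays of a genotype come from separate mice.

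The deposited values are log2 expression values per probe set, and per the submitters' processing notes they were made with RMA, which corrects background, normalizes between arrays and summarises the probes of each probe set. The version of RMA and the software that ran it are not given in the sources used here. The deposited table holds 45101 probe sets with values between 1.64 and 14.44, and the array medians lie between 5.26 and 5.31. These log2 values were used as the authors deposited them. RMA brings the arrays to a common distribution, so a change shared by most genes would not be visible, and it shrinks differences among dim probe sets. No detection calls were used here, so low signal could not be told from background. The number of arrays limits the precision.

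The 64 control probe sets of the array were left out, which leaves 45037 probe sets for testing. GEO's platform annotation names 1 gene symbol for 34958 probe sets and several symbols for 932, and it does not list 9160 of the tested probe sets, which stay unnamed here. No gene was named from a probe set with several symbols. By Entrez identifier, 34754 of the probe sets with 1 symbol matched the RefSeq gene table of mouse assembly GRCm38.p6, and the match changed 0 symbols. That table was used only for names and for which genes neighbour each other, because the array files name no genome build, so no coordinates are given. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 18193 genes.

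Heterozygous was compared with wild-type in limma 3.58.1 under R 4.3.3, with lmFit and eBayes and no covariates, and p-values were adjusted by the Benjamini-Hochberg method. A gene or probe set was said to rise or fall at an adjusted p under 0.05. Differences are heterozygous minus wild-type on the log2 scale with their standard error (SE), and group levels are given as mean ± SD over 3 arrays. For single probe sets an exact two-sided permutation test was run as well, whose smallest possible p is 0.1 with 3 arrays against 3. Shifts of 39 gene lists were tested with camera at its preset inter-gene correlation of 0.01, where a list had at least 5 measured genes, which held for 37 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in a single direction without comparing them with other genes, were run beside it. The share of changed genes within 20 Mb of Id4 was compared with that of all other placed genes by Fisher's exact test, two-sided.

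The gene lists, the tests, the alternatives and the rule for naming genes were set before the data were examined. The rule names Id1 to Id4, the 15 largest rises and the 15 largest falls among genes past the threshold whose groups do not overlap, and up to 4 members with the smallest unadjusted p in each shifted list and in the lists on cell cycle, apoptosis, glucocorticoid response, B-cell identity, T cells, macrophages, neutrophils and erythroid cells. Other genes named were chosen after their values were seen. They are some of the other called members of the lists, some of the called genes near Id4 and the genes named in the other observations, as is a list of pancreatic acinar genes.

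The alternatives were quantile normalization or median centring on top of the deposited values, eBayes with an intensity trend or in its robust form, array weights, leaving out dim probe sets whose mean lies at or below the median of 5.29, the replicate number as a block, leaving out each array in turn, the mean of all probe sets of a gene, an adjusted p under 0.10, a fold of at least 1.5, and for the genes near Id4 a window of 10 Mb, the whole chromosome and an unadjusted p under 0.01. Leaving out each array for the genes near Id4 was added after the data were seen.

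The gene test was checked on simulated arrays with the means of the 18193 genes for this comparison. Their spreads were those of the eBayes fit, which are drawn toward a common value, and not each gene's own SD. It recovered 25 of 67 genes seeded with a log2 change of 0.3, 67 of 67 with 0.6 and 64 of 66 with 1, and 10 of its 166 calls were false. A list seeded with a shift of -0.2 was recovered and 0 other lists were called. Genes were drawn independently of each other in a single run, so false calls of lists whose genes vary together were not checked. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.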

Results

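Expression was measured on 6 arrays of CD19-positive splenic B cells from 1-month-old TCL1-transgenic mice, 3 arrays of Id4 heterozygous and 3 of Id4 wild-type animals. TCL1 is an oncogene whose expression in B cells of transgenic mice leads to a disease resembling chronic lymphocytic leukaemia, and ID4 belongs to the inhibitor of DNA binding family, which pairs with E proteins and keeps them from binding DNA. The stated purpose of the comparison was to find genes regulated by Id4 that take part in the development of chronic lymphocytic leukaemia. Levels are deposited log2 RMA values, and differences are heterozygous minus wild-type. The correlation between arrays across probe sets was 0.9978 to 0.9983 within a genotype and 0.9968 to 0.9973 between genotypes. The first principal component held 38.7% of the variance and separated the genotypes, with heterozygous scores of -16.0 to -14.6 and wild-type scores of 13.5 to 16.5. Because the labels do not say that the arrays come from separate mice, the p-values measure the spread between these arrays, which may be technical.

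Id4 itself was dim on all arrays and did not differ detectably between the genotypes. The brightest of its 3 probe sets measured 3.81 ± 0.20 in heterozygous and 3.72 ± 0.17 in wild-type arrays (SD, n = 3 each), a difference of 0.09 with a 95% confidence interval of -0.19 to 0.37 and a limma adjusted p of 0.78. This probe set lay at percentile 27.8 of all probe sets by mean level. The other Id4 probe sets, with mean levels of 2.44 and 2.25, differed by -0.10 and -0.03 with adjusted p of 0.74 and 0.91. Exact two-sided permutation p-values for the Id4 probe sets were 0.6, 0.6 and 0.9, where the smallest possible value is 0.1. The sign of the Id4 difference turned with the mean of all its probe sets (-0.013), without heterozygous replicate 2 (-0.00061) and without wild-type replicate 3 (-0.0050). The labels do not say which part of Id4 the mutation removes, so these probe sets neither bear out nor contradict the genotype labels. The related genes Id1, Id2 and Id3, measured at 4.86, 8.02 and 8.35 in heterozygous arrays, gave differences of -0.06, -0.05 and -0.14 with adjusted p of 0.80, 0.66 and 0.16. The Id2 difference turned to 0.12 with the mean of its probe sets, and the Id1 difference to 0.029 without wild-type replicate 1.

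Of 18193 genes, 438 changed between the genotypes at an adjusted p under 0.05 in limma, 246 rising and 192 falling in heterozygous cells. Most changes were small. The median size of a called difference was 0.38 on the log2 scale, a fold of 1.30, and 70 genes reached a fold of 1.5, of which 38 rose and 32 fell. At an unadjusted p under 0.05, 2990 genes passed. The groups did not overlap for 4245 genes, or 23.3% where chance gives 10%. Over 45037 probe sets, 365 rose and 765 fell. The lists of other cell types and of sex-linked genes held 38 of the 438 called genes. These lists are short, and the share called differed between them. All 4 measured sex-linked genes were called, 13 of 17 macrophage and monocyte genes, 8 of 13 erythroid genes and 0 of 12 stromal and endothelial genes. The count therefore does not show how many of the other calls come from B cells. With an array left out, fewer genes passed, with 150, 159 and 184 genes without heterozygous replicates 1, 2 and 3, and 153, 170 and 209 without wild-type replicates 1, 2 and 3. Falls outnumbered rises without heterozygous replicate 2 (71 rising, 88 falling). With an intensity trend in eBayes 1408 genes passed, and 1040 passed with dim probe sets left out.

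The largest rises were those of Hspa1b and Hspa1a, which encode the inducible HSP70 chaperones. Hspa1b measured 11.1 ± 0.027 in heterozygous and 9.49 ± 0.053 in wild-type arrays (SD, n = 3 each), a 3.08-fold rise with a log2 difference of 1.62 (SE 0.04, limma adjusted p 6.5e-05). Its 3 probe sets rose by 1.61 to 1.62, and the single probe set of Hspa1a rose by 1.62 (SE 0.08). These genes are near-identical copies, so a probe set may read both and the share of each is uncertain. Adamdec1, a metalloprotease of macrophages and dendritic cells, rose by 1.29 (SE 0.11). The next rises, of 0.68 to 0.84, were in the neuronal phosphoprotein gene Crmp1 (0.84), D13Ertd608e (0.83), the endoplasmic reticulum membrane protein gene Vapb (0.82), Cd163 (0.78), which encodes the haemoglobin scavenger receptor of macrophages, Lin7c (0.78), Ddit4 (0.78), an inhibitor of mTORC1, the actinin gene Actn1 (0.75), Zfp982 (0.74), A430093F15Rik (0.72), Max (0.71), the dimer partner of MYC, Clec4n (0.71), which encodes dectin-2, and Treml4 (0.68), a receptor of splenic myeloid cells. Probe sets of the same gene did not always move alike. Among all called genes, 162 had another probe set with a mean above 5.29. In 138 of these all such probe sets differed in the same direction, and in 58 another was called the same way. With the mean of all probe sets, Vapb differed by 0.30, Lin7c by 0.47 and Actn1 by 0.49, and Zfp982 by 0.18 with an adjusted p of 0.23. The A430093F15Rik call was lost without heterozygous replicate 2 (adjusted p 0.053).

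The largest falls included genes of red cells, of the pancreas and of the Y chromosome. Zfp979, a zinc finger gene, fell from 4.20 ± 0.33 to 2.41 ± 0.16 (SD, n = 3 each), a log2 difference of -1.79 (SE 0.17, limma adjusted p 0.0036). Its heterozygous level lies below the lower quartile of each array (3.57 to 3.63), where signal was not told from background, so the size of this fall is uncertain. The water channel gene Aqp1 fell by 1.42 (SE 0.07). Among red-cell genes, the haem synthesis enzyme gene Alas2 fell by 1.14, the carbonic anhydrase gene Car1 by 1.14, Rhag by 1.13 (to a level of 3.22, also below that quartile, so its size is uncertain as well), Slc4a1, which encodes the band 3 anion exchanger, by 1.03 and Hemgn by 1.02. The pancreatic enzyme genes Cela2a and Cpb1 fell by 1.31 (SE 0.17) and 1.30 (SE 0.21). Both were dim, with means of 4.98 and 4.40 over the 6 arrays, so the sizes of these falls are uncertain. The Cela2a call was lost without wild-type replicates 1 or 3 and the Cpb1 call without wild-type replicate 1 or any heterozygous replicate, with adjusted p of up to 0.059 for Cela2a and 0.12 for Cpb1. A probe set annotated to the microRNA gene Mir1931 is also in this ranking, but which transcript it reads is not known, so no value is given. Further falls were those of Apobec3 (-1.07, SE 0.06), a cytidine deaminase that restricts retroviruses, Plcxd2 (-1.01), the G protein-coupled receptor gene Gpr132 (-0.99) and the Y-linked Eif2s3y (-0.93), and the Y-linked Kdm5d fell by 1.00. Of the 30 genes in this ranking, the other 14 rises and 13 falls kept their call with each array left out in turn.

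**Figure D1:**
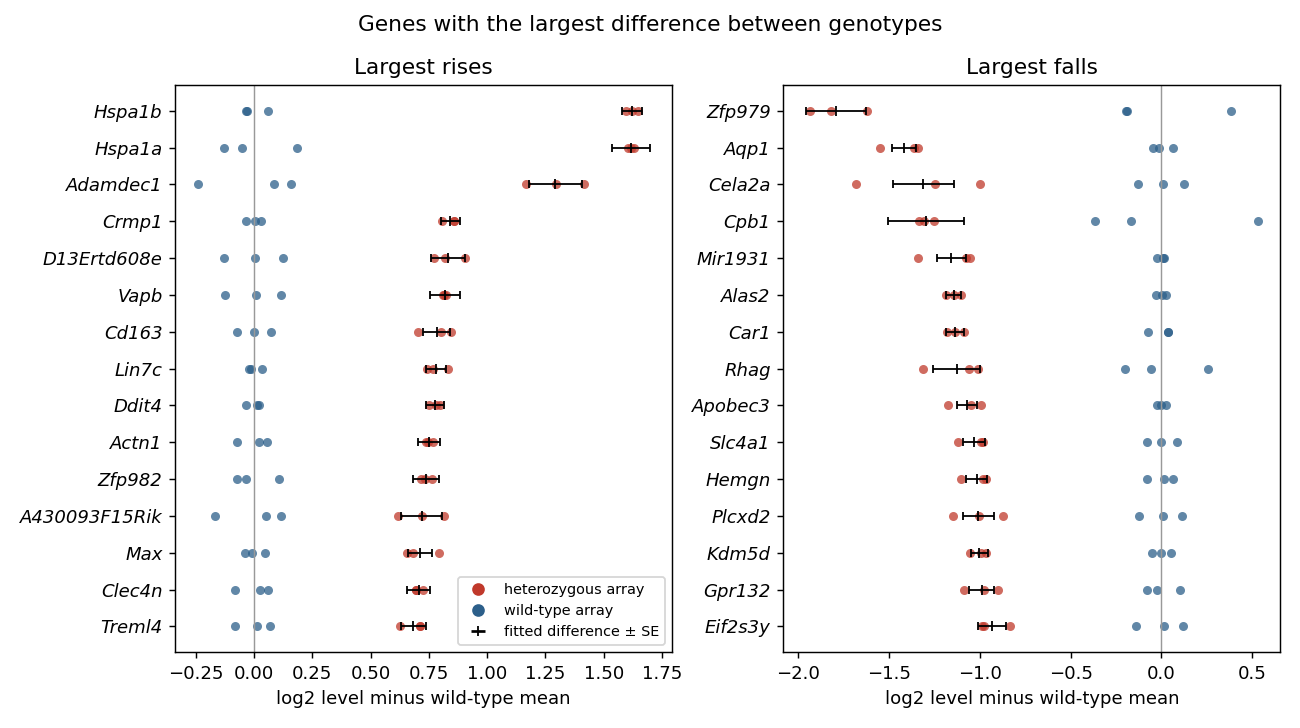
Log2 level minus the wild-type mean (horizontal axis) for the 15 genes with the largest rise (left) and the 15 with the largest fall (right), with a red point per heterozygous array, a blue point per wild-type array, and the fitted difference ± SE in black (n = 3 arrays per genotype). The heterozygous points of each gene lie to the same side of all its wild-type points, and the fitted differences run from 1.62 for Hspa1b to -1.79 for Zfp979.

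Sex-linked transcripts differed between the genotypes. Xist, the non-coding RNA of the inactive X chromosome, was high in all arrays and rose by 0.62 in heterozygous cells (12.2 ± 0.074 against 11.6 ± 0.047, SD, n = 3 each, limma adjusted p 0.0029). The Y-linked genes Kdm5d, Eif2s3y and Uty fell by 1.00, 0.93 and 0.74, with adjusted p of 0.00055, 0.0028 and 0.0017. The other Xist probe sets rose by 0.99 and 1.02. Those of Kdm5d differed by -0.60 and 0.09, the latter dim at percentile 19.4 of all probe sets. With the mean of its probe sets Kdm5d differed by -0.50. All 4 measured genes of this list passed, also when adjusted over the list alone, where 1 rose and 3 fell. This difference in sex-linked transcripts, like that of a control probe set for 18S ribosomal RNA (1.06 higher in heterozygous arrays), stands beside every gene group described here, since all follow the same 2 groups of arrays.

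**Figure D2:**
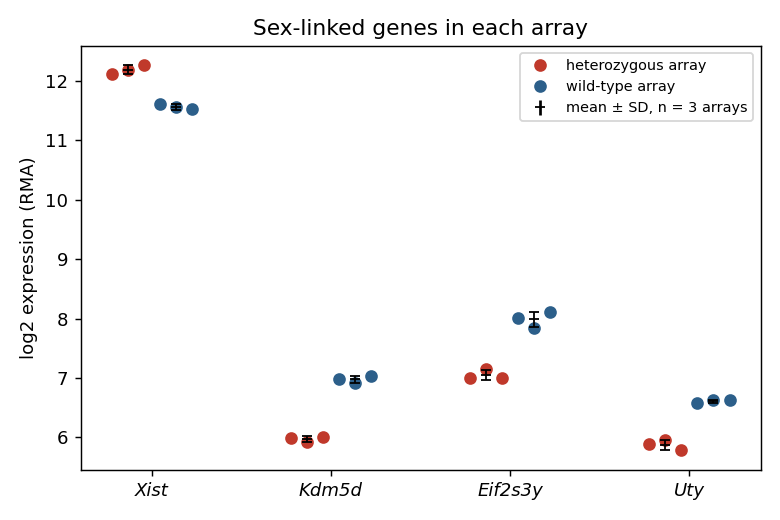
Log2 expression (RMA, vertical axis) of 4 sex-linked genes in each array, with heterozygous arrays in red, wild-type arrays in blue, and the mean ± SD over 3 arrays in black. Xist lies near 12.2 in heterozygous and 11.6 in wild-type arrays, and the Y-linked Kdm5d near 5.98 and 6.98.

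Markers of other blood cells moved in opposite directions. Of 17 measured macrophage and monocyte genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median difference of 0.37 and a camera adjusted p of 6.76e-11 (adjusted p = 0.11 with an estimated correlation). The rises were led by the complement genes C1qb (0.60, SE 0.04), C1qc (0.55) and C1qa (0.53) and the adhesion receptor gene Vcam1 (0.52), and they included Hmox1, Spic and Slc40a1, which serve haem and iron handling in splenic red pulp macrophages, by 0.44, 0.43 and 0.47. The lysozyme gene Lyz2 fell by 0.25. Calls of 7 of these 13 genes stood with each array left out in turn. Of 14 genes of neutrophils and granulocyte precursors, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.22 and a camera adjusted p of 3.26e-06 (adjusted p = 0.11 with an estimated correlation). S100a8 and S100a9, which encode the subunits of calprotectin, rose by 0.43 and 0.42, and the granule genes Camp and Ngp by 0.33 and 0.32. The S100a9 call was the single call of this list that stood with each array left out in turn.

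Erythroid genes fell. Of 13 measured members, 8 fell and 0 rose (11 and 0 adjusted over the list alone), all 13 had lower means in heterozygous arrays, and the median was -0.63 with a camera adjusted p of 2.08e-16 (adjusted p = 0.029 with an estimated correlation). Besides the 5 red-cell genes above, Klf1, the erythroid transcription factor gene, fell by 0.71, Car2 by 0.63 and Ermap by 0.62. The alpha-globin probe set Hba-a1 was dim (3.81 against 3.88) and differed by -0.07 (adjusted p 0.69). All 8 calls stood with each array left out in turn. Of 11 dendritic cell genes, 4 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.33 and a camera adjusted p of 1.65e-06 (adjusted p = 0.14 with an estimated correlation). Itgax, which encodes CD11c, fell by 0.59 (SE 0.04), Siglech, a receptor of plasmacytoid dendritic cells, by 0.50, Batf3 by 0.33 and Cst3 by 0.23. The Batf3 and Cst3 calls were lost with any array left out, at adjusted p of up to 0.15 and 0.12, and the Batf3 call also with quantile normalization, median centring and robust eBayes.

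**Figure D3:**
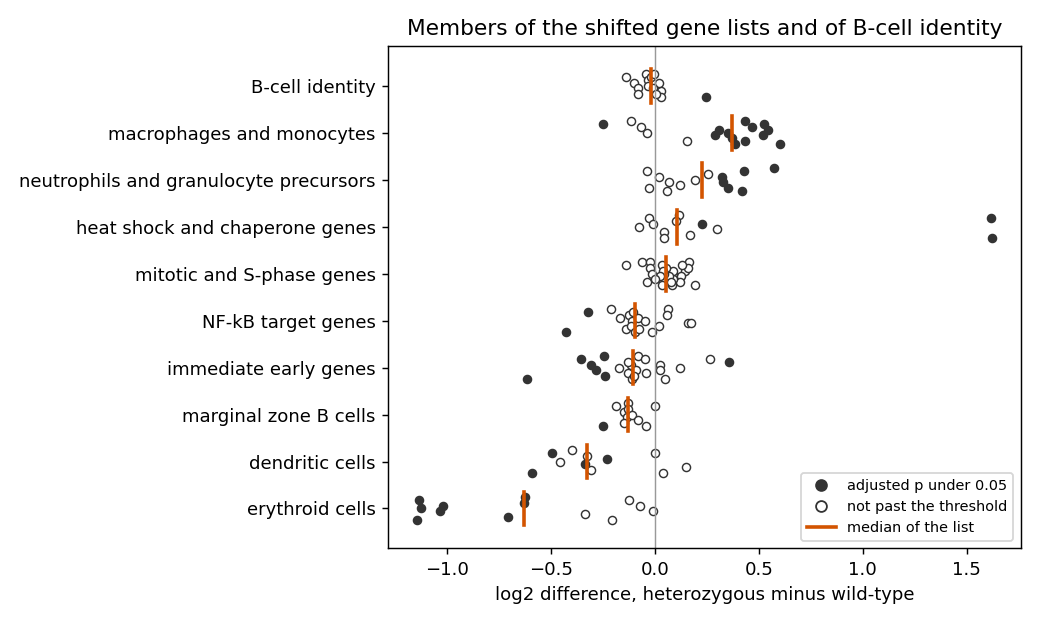
Log2 difference, heterozygous minus wild-type (horizontal axis), of each measured member of the B-cell identity list and the 9 shifted lists, with filled points for adjusted p under 0.05, open points for the rest, and an orange bar at the list's median. The macrophage median lies at 0.37, the erythroid median at -0.63 and the B-cell identity median at -0.02.

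In the remaining lists of other cell types no shift passed the threshold. Of 15 T-cell genes 1 rose, Cd3g by 0.31 (2 rose and 2 fell adjusted over the list alone, camera adjusted p 0.88), and the Cd3g call was lost with any array but heterozygous replicate 1 left out (adjusted p up to 0.13). Cd4, Cd5 and Lat differed by -0.28, 0.25 and -0.20 with adjusted p of 0.064, 0.082 and 0.11, and Cd4 by -0.18 with the mean of its probe sets. Of 11 NK-cell genes 0 passed (3 fell adjusted over the list alone, camera adjusted p 0.22). Of 10 platelet and megakaryocyte genes Clec1b rose by 0.32 and Itgb3 fell by 0.35 (1 and 1 adjusted over the list alone, camera adjusted p 0.91), with a median of -0.0062 and a mean of 0.0080. Of 12 stromal and endothelial genes 0 passed (1 fell adjusted over the list alone, camera adjusted p 0.64), with a median of 0.0099 and a mean of -0.02, where camera also pointed down. The Clec1b call was lost with any array left out and the Itgb3 call without replicate 1 of either genotype (adjusted p up to 0.12). Itgb3 differed by -0.21 with the mean of its probe sets and lost its call (adjusted p 0.057).

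B-cell identity genes showed no shift past the threshold as a group. Of 15 measured members 1 rose, Cd72 by 0.24 (SE 0.04), with 1 also adjusted over the list alone, a median of -0.02 and a camera adjusted p of 0.46. The Cd72 call was lost with any array left out (adjusted p up to 0.12). Cd37, Cd22 and Blk differed by -0.14, -0.10 and -0.08 with adjusted p of 0.18, 0.31 and 0.39. Marginal zone B-cell genes were lower as a group. Of 11 members Cd1d1, which encodes the lipid-presenting molecule CD1d, fell by 0.25 (4 fell adjusted over the list alone), 10 had lower means, and the median was -0.13 with a camera adjusted p of 2.68e-05 (adjusted p = 0.21 with an estimated correlation). Tm6sf1, Cr2 and Dtx1 differed by -0.19, -0.15 and -0.14 with adjusted p of 0.085, 0.12 and 0.15, and with the mean of their probe sets Tm6sf1 differed by -0.094 and Dtx1 by -0.014. The Cd1d1 call was lost with any array left out (adjusted p up to 0.14). Of 6 follicular genes 0 passed (0 adjusted over the list alone, camera adjusted p 0.46), and likewise 0 of 10 transitional genes (0 adjusted over the list alone, camera adjusted p 0.46). Of 10 B-1 cell genes 0 passed over all genes and 5 rose adjusted over the list alone, with a median of 0.08 and a camera adjusted p of 0.098. Of 12 pro-B and pre-B genes Myb rose by 0.28 and Kit fell by 0.53, or by 0.28 with the mean of its probe sets (1 rose and 2 fell adjusted over the list alone, camera adjusted p 0.92), with median and mean at -0.03 where camera pointed up. Of 8 germinal centre genes Rgs13 rose by 0.68 (2 rose adjusted over the list alone, camera adjusted p 0.64). Of 13 plasma cell genes Igha fell by 0.36, Irf4 by 0.27 and Tnfrsf17 by 0.38 (1 rose and 3 fell adjusted over the list alone, camera adjusted p 0.24, fry adjusted p 0.040). The Rgs13 and Igha calls stood with each array left out in turn, and the Myb, Kit, Irf4 and Tnfrsf17 calls did not (adjusted p up to 0.15). The Kit call was also lost with quantile normalization and median centring. Of 3 measured immunoglobulin heavy chain constant genes, too few for the set test, Igha was the single call, also adjusted over the list alone. Ighm differed by -0.02 in its brightest probe set, which held the highest value of each array, so that near the top of the range a change would not show, while differences of its other probe sets ran from -2.18 to 0.69.

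Stress and activation genes moved in different directions. The heat shock list shifted up, with 3 of 12 genes rising (4 adjusted over the list alone), a median of 0.11 and a camera adjusted p of 8.4e-05 (adjusted p = 0.25 with an estimated correlation). The rises include the near-identical Hspa1a and Hspa1b, and the other 10 genes had a median of 0.07 and an unadjusted camera p of 0.015. Besides Hspa1a and Hspa1b, the co-chaperone gene Dnajb1 rose by 0.23 (SE 0.04), a call lost with any array left out (adjusted p up to 0.13), and Hspb1 differed by 0.30 with an adjusted p of 0.13. Of 22 immediate early genes 6 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.10 and a camera adjusted p of 2.68e-05 (adjusted p = 0.21 with an estimated correlation). Atf3, a stress-induced transcription factor gene, fell by 0.61 (SE 0.04), Fosb by 0.35, Nr4a1 by 0.31, Klf4 by 0.28, Egr1 by 0.24 and Junb by 0.24, while Egr2 rose by 0.36. The Atf3 call stood with each array left out in turn, and the Fosb call was lost without replicate 1 of either genotype (adjusted p up to 0.058). The Nr4a1, Klf4, Egr1, Junb and Egr2 calls were lost with any array left out (adjusted p up to 0.16). Klf4 differed by -0.19 and Egr2 by 0.28 with the mean of all probe sets, and both lost their call (adjusted p 0.13 and 0.11), as Egr2 also did with median centring and robust eBayes. Of 19 NF-kB target genes, the chemokine genes Ccl3 and Ccl4 fell by 0.43 and 0.32 (6 fell and 1 rose adjusted over the list alone), with a median of -0.09 and a camera adjusted p of 0.0018 (adjusted p = 0.14 with an estimated correlation). Tnfaip3 and Cd83 differed by -0.17 and 0.16 with adjusted p of 0.083 and 0.11. The Ccl3 call was lost without heterozygous replicates 1 or 3 or wild-type replicates 1 or 2 (adjusted p up to 0.056), and the Ccl4 call with any array but heterozygous replicate 1 left out (adjusted p up to 0.12).

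Glucocorticoid response genes showed no shift past the threshold by camera as a list, with a median of -0.07, a mean of 0.02 and a camera adjusted p of 0.77 pointing down (fry adjusted p 0.022). Of 15 members Ddit4 and Sgk1, a kinase gene, rose by 0.78 (SE 0.04) and 0.36 (SE 0.05), and 3 rose and 6 fell adjusted over the list alone. Klf9 and Nr3c1, which encodes the glucocorticoid receptor, differed by -0.21 and -0.17, each with an adjusted p of 0.094, and by -0.13 and -0.082 with the mean of their probe sets. The Ddit4 call stood with each array left out in turn, and the Sgk1 call was lost with any array but wild-type replicate 3 left out (adjusted p up to 0.084).

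Cell cycle genes differed little. Of 27 mitotic and S-phase genes 0 passed singly (0 adjusted over the list alone), 21 had higher means in heterozygous arrays, and the list shifted up by a median of 0.05 with a camera adjusted p of 0.016 (adjusted p = 0.44 with an estimated correlation). This shift was lost without heterozygous replicates 1 or 2 or wild-type replicate 1 (adjusted p up to 0.078), with dim probe sets left out and with the mean of probe sets. The replication genes Uhrf1 and Mcm5 and the mitotic kinase gene Aurkb differed by 0.19, 0.15 and 0.13 with adjusted p of 0.15, 0.17 and 0.21, and the proliferation marker gene Mki67 by -0.14 with 0.16. Uhrf1 differed by 0.10 with the mean of its probe sets. Of 16 cell cycle inhibitor and checkpoint genes Cdkn2b, which encodes the CDK4 and CDK6 inhibitor p15, rose by 0.22 (SE 0.04, adjusted p 0.0496), with 1 also adjusted over the list alone, and this call was lost in 11 of 13 settings, among them any array left out (adjusted p up to 0.17), quantile normalization, median centring, an intensity trend and robust eBayes. The list had a median of -0.03, a mean of 0.0021 and a camera adjusted p of 0.92 pointing down. Cdkn2c, Gadd45b and Sesn1 differed by 0.17, -0.12 and -0.11 with adjusted p of 0.20, 0.27 and 0.23, and Gadd45b by -0.057 with the mean of its probe sets. Of 11 G1 cyclin and MYC genes Ccnd1, which encodes cyclin D1, fell by 0.39 (1 adjusted over the list alone, camera adjusted p 0.92), and differed by -0.19 with the mean of its probe sets, where its call was lost (adjusted p 0.12).

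The apoptosis lists showed no shift past the threshold by camera, and a single gene in each passed. Of 15 pro-apoptotic genes Bcl2l11, which encodes the BH3-only protein BIM, rose by 0.41 (SE 0.06, limma adjusted p 0.021), and 2 rose adjusted over the list alone. With the mean of its 5 probe sets Bcl2l11 differed by 0.24, and its call was lost without wild-type replicate 2 or any heterozygous replicate (adjusted p up to 0.094). Bmf, Tnfrsf10b and Hrk differed by 0.21, 0.17 and -0.12 with adjusted p of 0.10, 0.38 and 0.36, and with the mean of their probe sets Tnfrsf10b differed by 0.077 and Hrk by -0.057. The median of the list was -0.0021 and its mean 0.03, with a camera adjusted p of 0.77 pointing up. Of 11 anti-apoptotic genes Pim1, which encodes a pro-survival kinase, fell by 0.43 (SE 0.04, limma adjusted p 0.0051, 1 adjusted over the list alone), a call that stood with each array left out in turn. Bcl2l2, Birc3 and Birc2 differed by -0.12, -0.11 and -0.10 with adjusted p of 0.39, 0.24 and 0.30 (Bcl2l2 by 0.043, with the sign turned, with the mean of its probe sets), and the camera adjusted p of the list was 0.26 (fry adjusted p 0.013).

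The lists closest to ID4 showed no shift past the threshold. Of 7 ID and E-protein genes 0 passed (2 fell adjusted over the list alone, camera adjusted p 0.24), and of 11 E-protein target genes 0 passed (0 adjusted over the list alone, camera adjusted p 0.77). The same held for other pathways, where 0 of 18 B-cell receptor signalling genes (0 adjusted over the list alone, camera adjusted p 0.24), 0 of 15 AKT and FOXO genes (1 fell adjusted over the list alone, camera adjusted p 0.40), 0 of 13 TGF-beta genes (0 adjusted over the list alone, camera adjusted p 0.40), 0 of 15 Notch genes (0 adjusted over the list alone, camera adjusted p 0.97), 0 of 10 MHC class II genes (0 adjusted over the list alone, camera adjusted p 0.22) and 0 of 17 ribosomal protein genes (0 adjusted over the list alone, camera adjusted p 0.46) passed. Of 20 interferon-stimulated genes Rsad2 fell by 0.50, Stat2 fell by 0.25 and Ifi27l2a rose by 0.30 (2 rose and 3 fell adjusted over the list alone, camera adjusted p 0.84), with a median of 0.0010 and a mean of -0.02. Of 19 WNT pathway genes the receptor gene Fzd6 rose by 0.62 and Ccnd1 fell by 0.39 (1 and 1 adjusted over the list alone, camera adjusted p 0.91), with a median of -0.0049 and a mean of 0.02. Of 15 homing genes the integrin gene Itga4 fell by 0.24 (1 adjusted over the list alone, camera adjusted p 0.22). Of 14 genes of DNA methyltransferases and chromatin silencers Tet2, a dioxygenase gene of DNA demethylation, fell by 0.30 (1 adjusted over the list alone, camera adjusted p 0.46). The calls of Rsad2, Stat2, Ifi27l2a, Fzd6, Ccnd1, Itga4 and Tet2 were each lost with at least 1 array left out (adjusted p up to 0.14). Ccnd1, Tet2, Stat2 and Itga4 differed by -0.19, -0.21, -0.15 and -0.12 with the mean of all probe sets and lost their calls (adjusted p 0.12, 0.12, 0.16 and 0.30), and Tet2 lost its call with median centring as well. In total 9 of 37 tested lists shifted by camera, the erythroid list alone passed with an estimated correlation, and fry called 12, the 9 of camera and the anti-apoptotic, glucocorticoid response and plasma cell lists.

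Genes near Id4 were not called detectably more often than others. Within 20 Mb of Id4, 8 of 308 genes were called, or 2.60%, against 430 of 17723 other genes, or 2.43%, an odds ratio of 1.07 with a 95% confidence interval of 0.46 to 2.16 (Fisher's exact test, two-sided, p = 0.85). The odds ratio turned below 1 within 10 Mb (0.51, 2 of 158 genes). It also did so without heterozygous replicates 1, 2 or 3 (0.776, 0.731 and 0.953) and without wild-type replicate 3 (0.836). The called neighbours with the largest differences were Tmem14c (-0.73), a mitochondrial protein gene of haem synthesis in erythroid cells, and Cdc14b (-0.47). The Tmem14c call stood with each array left out in turn, and the Cdc14b call was lost in 5 of the 6 cases (adjusted p up to 0.14).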

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

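A control probe set of the array, outside the main measurement, differed between the genotypes. The probe set for the 5' end of mouse 18S ribosomal RNA was higher in heterozygous arrays by 1.06 (SE 0.19, limma adjusted p 0.036), at 7.86 ± 0.24 against 6.80 ± 0.35 (SD, n = 3 each). The probe sets for the middle and the 3' end of the same RNA differed by 0.51 and 0.26, with adjusted p of 0.097 and 0.29, and in all 3 the genotypes did not overlap. These differences follow the same 2 groups of arrays as every gene group of the main comparison. The control probe set for the 5' end of the transferrin receptor was lower by 0.34 (SE 0.07, limma adjusted p 0.048), at 4.36 ± 0.11 against 4.70 ± 0.026 (SD, n = 3 each). Those for the middle and the 3' end differed by -0.12 and -0.13, with limma adjusted p of 0.41 and 0.25. The 3' probe set was the brightest, at 6.67 against 6.80, and in the middle probe set the genotypes overlapped.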

How the results depend on the processing

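Counts of changed genes depended on the settings. All 438 called genes kept their direction under every setting in which they were tested, except that 437 did with the mean of all probe sets. Much of this was fixed in advance. The forms of eBayes and the replicate block leave each difference as it is. Leaving out an array cannot turn the direction of a gene whose groups do not overlap. Quantile normalization, median centring, robust eBayes, array weights and the mean of probe sets gave 490, 420, 400, 513 and 421 genes. Of these, 419, 391, 400, 436 and 325 were among the 438, so the mean of probe sets changed the called genes more than its total shows. Median centring raised the share of rises among calls from 56.2% to 63.8%, while the scaling settings moved the median difference of all genes to at most 0.024. Other settings moved the counts further, and apart from what their construction implies (fewer genes tested, fewer arrays, another threshold) the cause was not tested. An intensity trend gave 1408 genes (745 rising, 663 falling) and 2927 probe sets. Leaving out dim probe sets gave 1040 genes (554 rising, 486 falling) and 2574 probe sets, and it left no value for Id4. An adjusted p under 0.10 gave 837 genes (439 rising, 398 falling) and 2137 probe sets, and a fold of at least 1.5 gave 70 genes (38 rising, 32 falling).

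With an array left out, 150 genes (without heterozygous replicate 1) to 209 genes (without wild-type replicate 3) passed, 71 to 112 rising and 67 to 97 falling (more falling than rising only without heterozygous replicate 2, 88 against 71, or 44.65% rising), with 317 to 496 probe sets and 8 to 9 lists. The Id4 difference ran from -0.0050 to 0.19, and that of Id1 from -0.15 to 0.029. The odds ratio near Id4 ran from 0.73 to 1.15 over the leave-one-out settings, was 0.51 within 10 Mb, and was 1.06 and 1.10 for the whole chromosome and for an unadjusted p under 0.01. With the mean of all probe sets, Id4 differed by -0.013, Id2 by 0.12 and Bcl2l2 by 0.043, each with the sign turned. Of the 112 called genes followed through the settings (those named, all called list members and all called genes near Id4), 53 kept their call with each array left out in turn, 45 kept it under all settings, and 25 lost it with any array left out. Camera with an estimated correlation called 1 list in place of 9, and fry called 12, adding the anti-apoptotic, glucocorticoid response and plasma cell lists (adjusted p 0.013, 0.022 and 0.040).

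The replicate number as a replicate block gave 108 genes (57 rising, 51 falling), 104 of them shared with the 438, and 191 probe sets, with 9 lists shifted as before. Some calls that stood with each array left out in turn were lost with the block. Among them were those of Rgs13, Igha, Rhag and Ermap (limma adjusted p 0.067, 0.069, 0.076 and 0.061). Arrays with the same number did not deviate together, since the correlations of their deviations from the group means were 0.0083, -0.062 and -0.13, and no heterozygous array correlated best with the wild-type array of its own number.

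The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 438 genes, 1130 probe sets and 9 lists, and was the only 1 of the 10 to reach each count, where the highest of the other splits gave 0 genes, 0 probe sets and 1 list. Signal over background limits the Id4 result, since its brightest probe set lies at percentile 27.8 of all probe sets.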

Other observations

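Most pancreatic enzyme genes had lower means in heterozygous arrays. The tests of this part were chosen after the result was seen, except the count of called genes with a called neighbour. The pancreatic acinar list, which was added after values of Cela2a, Cpb1, Cela3b, Prss2, Clps, Ctrb1 and Cel had been seen, had 20 measured members, of which 7 fell, 18 had lower means and the median was -0.32. Colipase (Clps) fell by 0.64, Reg1 by 0.48, chymotrypsinogen (Ctrb1) by 0.58, Cpa1 by 0.52 and Pnliprp1 by 0.70. Of the called members, Cela2a, Cpb1, Reg1, Cpa1 and Pnliprp1 had means below the median of 5.29. Reg1 was the dimmest of them, at 3.62 against 4.11, so the sizes of these falls are uncertain. The brightest member of the list, Cela1, lay at 7.77 against 7.71 and differed by 0.06 (limma adjusted p 0.70). The Cpa1 and Pnliprp1 calls were each lost in 4 of the 6 cases with an array left out (adjusted p up to 0.087 and 0.098). The other 10 measured heat shock genes, without Hspa1a and Hspa1b, had a median of 0.07 and 7 of them were higher in heterozygous arrays. Camera at the preset correlation pointed up with an unadjusted p of 0.015, and an estimated correlation was not tried for these genes. Within 1 Mb of Hspa1a and Hspa1b, 2 of 99 genes were called, Aif1 and C2, or 2.02% against 2.42% of other genes (Fisher's exact test, two-sided, p = 1).

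Probe sets annotated to Ighm, the constant region gene of immunoglobulin M, differed in opposite directions. A probe set at percentile 88.7 of all probe sets in brightness measured 7.95 ± 0.019 in heterozygous and 10.1 ± 0.037 in wild-type arrays (SD, n = 3 each), a difference of -2.18 (SE 0.05, limma adjusted p 1.3e-05). Other Ighm probe sets rose by 0.69, 0.59 and 0.58, and the brightest, at 14.4 in both genotypes, differed by -0.02. That probe set held the highest value of each array, so this difference does not show whether Ighm changed.

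The 3 arrays of a genotype lay close together, with a median absolute difference between arrays of 0.079 to 0.091 within a genotype and 0.10 to 0.11 between genotypes. Xist lay at percentile 98.7 or above of all probe sets in each array, so arrays of 1 mouse would all be female and would not differ in Y-linked transcripts. The mean of the 3 Y-linked genes differed between genotypes by -0.89 (95% confidence interval -1.01 to -0.77), which argues against an array holding the RNA of 1 mouse. The largest range of the Y-linked mean within a genotype was 0.122. The smallest change of sex makeup in pools of 3 mice would give 0.585, if each mouse gave equal RNA and the arrays responded in proportion. Neither was checked, and a dampened response would lower that value. On those terms the range argues against separate pools that differ in makeup. The spread within a genotype of 40 genes that follow the mice or the dissection (sex-linked, erythroid, pancreatic and immunoglobulin genes) had a median SD of 0.086, at percentile 74.6 of 10000 random lists matched on brightness (median 0.081, 95% range 0.066 to 0.098). Repeats of 1 pool per genotype would give this. The test cannot decide, since the random lists come from the same arrays and their genes may vary between mice as well. A candidate explanation is that the p-values measure technical spread, while separate pools of matched makeup remain open, as does a difference by genotype.

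Genes of other cell types differed between the genotypes. The erythroid median minus the macrophage median was -1.003 (95% bootstrap interval -1.45 to -0.52). The bootstrap resampled the genes of each list, so its interval measures the spread among list members and not that between arrays or mice. In these arrays the opposite directions argue against a different share of B cells alone, since that would move both the same way. Of 13 acinar genes whose values had not been seen when the list was written, 11 were lower in heterozygous arrays (exact binomial p = 0.022). This test takes the genes as independent. Genes of the same tissue on the same arrays can move together, so the p-value can be too small. Some pancreatic tissue in the wild-type samples, which selection on CD19 should have removed, would give such lower means. Erythroid cells carried over in different numbers and a change of those cells by genotype cannot be told apart, since both predict the lower means seen for all 13 erythroid genes and the design confounds them. The abundant globin gene Hba-a1 stayed dim, at 3.81 against 3.88, so its probe set adds nothing.

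Called genes near each other were examined because the mice come from crossed strains, so that linked alleles could differ between the genotypes. Outside the fixed lists, 113 of 361 called genes had another called gene within 0.5 Mb, where 10000 random draws matched on brightness gave a median of 101 (95% range 80 to 123, permutation p = 0.20). The longest chain of called genes held 6 genes (random median 4, upper end of the 95% range 7, permutation p = 0.14), and it lies next to Ighm, with falls of Gpr132 (-0.99), Tedc1 (-0.54), Tmem121 (-0.45), Brf1 (-0.43) and Adssl1 (-0.42) and a rise of Crip2 (0.30). The Crip2 call was lost with any array left out (adjusted p up to 0.17), that of Tmem121 in 5 of the 6 cases, of Adssl1 in 2 and of Brf1 in 1, so these counts depend on calls that do not hold without every array. There were 5 chains of 4 genes, a length equal to the random median of the longest chain. In 4 of them directions were mixed, and in 1 all genes fell, with Apobec3 (-1.07), Cbx7 (-0.69), Cbx6 (-0.55) and D730005E14Rik (-0.46), where the D730005E14Rik call was lost in 5 of the 6 cases. Within 1 Mb of Ighm 7 of 29 genes were called, or 24.1% (Fisher's exact test, two-sided, p = 4.4e-06), but this window was picked because of the chain and is no independent evidence. Neither genome-wide test exceeded its random draws, so linked alleles and chance cannot be told apart here.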
